A study of Mus musculus with 16 samples.

How the data were processed

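Gene expression was measured by bulk RNA sequencing in microglia of C57BL/6 mice at 4 postmortem intervals, 0, 4, 6 and 12 h, with 4 libraries per interval and 16 in all. Per the labels' protocols, mice killed by cervical dislocation lay at room temperature for the interval, and cells were then freed mechanically and separated on Percoll at 4 °C. Viable cells (no DAPI uptake) with CD45 and CD11b but without Ly6c at the surface were sorted, and libraries followed a Lexogen protocol whose kit is not given in the sources used here. Whether the libraries cover whole transcripts or their 3' ends, mark strand or carry molecular identifiers is therefore unknown, and counting and Wilson intervals and floors of counts quoted here cover counting error only. The design text speaks of 16 mouse samples and does not state that each replicate is a separate animal, so p-values measure the spread between these samples, which may be partly technical.

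The deposited table holds whole-number counts of reads per gene, 1 column per library, not normalized. Per the file headers it has the column layout of featureCounts, with exon coordinates and the summed exon length of each Ensembl gene. The submitters' processing notes name Trim Galore, HISAT2 2.1.0, Picard 1.140, SAMtools 1.9, featureCounts 1.6.2 and the genome build GRCm38, with no role or order. The annotation release, the strand setting, the treatment of duplicate reads and the treatment of reads with several matches are not given in the sources used here. These choices bear on the values. Without strand, reads of overlapping or antisense genes cannot be told apart. Reads of small RNA genes with near-identical copies can be dropped or given to 1 copy, and removal of duplicates lowers the counts of the most abundant genes most.

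The table has 53801 genes, of which 53620 were given a symbol from a table of Ensembl names and 53706 are in GENCODE M21. For 52142 of them the start and end were the same as in that release, which also gave the gene classes. Coordinates are those of the count table on GRCm38. Library totals ran from 241237 to 595929 counts with a median of 349152, which is low for bulk RNA sequencing, and the median standard error over genes was 0.66 log2 units in each comparison with 0 h. Pairs of libraries within an interval differed by far more than counting noise (chi-square per degree of freedom of 5.08 or more), so each library was counted as 1 sample.

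Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM scaling, filterByExpr by interval, quasi-likelihood F test, two-sided), with 1 coefficient per interval fitted over all 16 libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 among the 6754 tested are called. The comparisons were each later interval with 0 h, 6 h with 4 h, 12 h with 6 h, all intervals together, and a linear trend with hours. Scaling factors lay between 0.939 and 1.08. CPM values in the text (counts scaled to the library total with these factors) are given as mean ± SD over 4 libraries. Fold changes are log2 values with their standard errors. The number of genes whose 95% interval of the log2 fold change lay between -1 and 1 was counted as well, since a p above the threshold does not show that a gene stayed the same.

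Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2), with its preset correlation of 0.01 between genes and again with an estimated correlation. Of 35 lists covering microglial states, stress and metabolic responses and markers of other cells, 27 entered the test, which needed 3 members, and p-values were adjusted over 81 tests. List tests between adjacent intervals were adjusted over all comparisons of pairs of intervals together, which are more tests. So were those with an estimated correlation in fits without the 4 h library 3 and the 6 h library 2. Counts of list members past the threshold are those of edgeR, given over all genes tested and adjusted over the list alone. Library measures were compared by exact permutation of all 70 assignments of 8 libraries, for which the smallest p is 0.0286. The share of variance between intervals used 100000 relabellings. Correlations of fold changes between intervals, which share the 0 h libraries, are set beside 100 simulations of unchanged groups.

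Genes were named by a rule: for each comparison with 0 h, the 8 largest rises and 8 largest falls among called genes with a mean CPM of at least 10, no overlap between the 4 later and the 4 earlier libraries, and a symbol that is not a provisional one; up to 4 members of each list with the smallest p; and a fixed panel of 18 genes. Where fewer than 5 genes passed, the 5 with the smallest p were named as not passing. The design, this rule, the lists and most alternatives were fixed before the data were examined.

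The pipeline was tested on simulated counts drawn from the means of these libraries. For the comparison of 12 h with 0 h over 6754 genes, it recovered 1.49% of 67 genes changed by a fold of 2, 38.8% of 67 changed by a fold of 4 and 65.2% of 66 changed by a fold of 8, with 2 false calls among 72. For 4 h with 0 h these shares were 2.99%, 37.3% and 63.6%, and for 6 h with 0 h 4.48%, 38.8% and 68.2%.

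The alternatives were DESeq2 size factors in edgeR, no filter on low counts, DESeq2 1.42.0 (Wald and likelihood ratio tests), the replicate number as a block, a minimum fold of 2, a fit of only the 8 libraries compared, an estimated correlation in camera, the 1000 most variable genes, and leaving out each library in turn. Added after the data were seen were fits without the 4 h library 3 and the 6 h library 2, list tests between adjacent intervals, removal of a trend on transcript length and GC content, and shares of counts by gene class. No library was left out of the reported tests. The values of some genes that the rule names are not reported here.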

Results

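Microglia, the resident macrophages of the brain, were profiled after 0, 4, 6 and 12 h between death and isolation, to ask how a postmortem delay alters their gene expression. Total counts per library were 276664, 340072, 449141 and 414314 at 0 h, 334247, 267882, 546717 and 403084 at 4 h, 595929, 488629, 358233 and 279364 at 6 h, and 300937, 241237, 318861 and 420940 at 12 h. Between 9188 and 11704 genes had at least 1 count in a library. At this depth 6754 genes could be tested, and Fos, Il1b, Tnf, Hspa1a, Rbm3 and Gapdh, which belong to the fixed panel, had too few counts.

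In the 4 h library 3 and the 6 h library 2, transcripts of astrocytes and oligodendrocytes, the supporting and myelinating glia of the brain, took a larger share of counts than in the other 14 libraries. Astrocyte markers made up 0.878% of counts (95% Wilson interval 0.854 to 0.903) in the former and 0.927% (0.901 to 0.954) in the latter, against at most 0.0752% elsewhere. Oligodendrocyte markers made up 0.867% (0.843 to 0.892) and 0.969% (0.942 to 0.997), against at most 0.108% elsewhere. Neuronal markers, at 0.113% and 0.103%, and endothelial markers, at 0.0157% and 0.0166%, lay within the range of the other libraries. Xist, the RNA that silences an X chromosome in female cells, had 80 and 18 counts in these libraries and 0 in the other 14, where 0 counts allow a CPM of up to 12.4 in the smallest library. Counts of Ddx3y, a gene of the Y chromosome, were 52 and 10 there and above 0 in all 16 libraries. Relative to the library total, its CPM was lowest in the 6 h library 2, at 20.5 against 72.1 to 260 in all others. Fos, an immediate early gene, had 195 and 16 counts there and 0 to 11 in the other 14. Every count of genes was therefore also taken without these libraries, an alternative chosen after the data were seen.

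**Figure D1:**
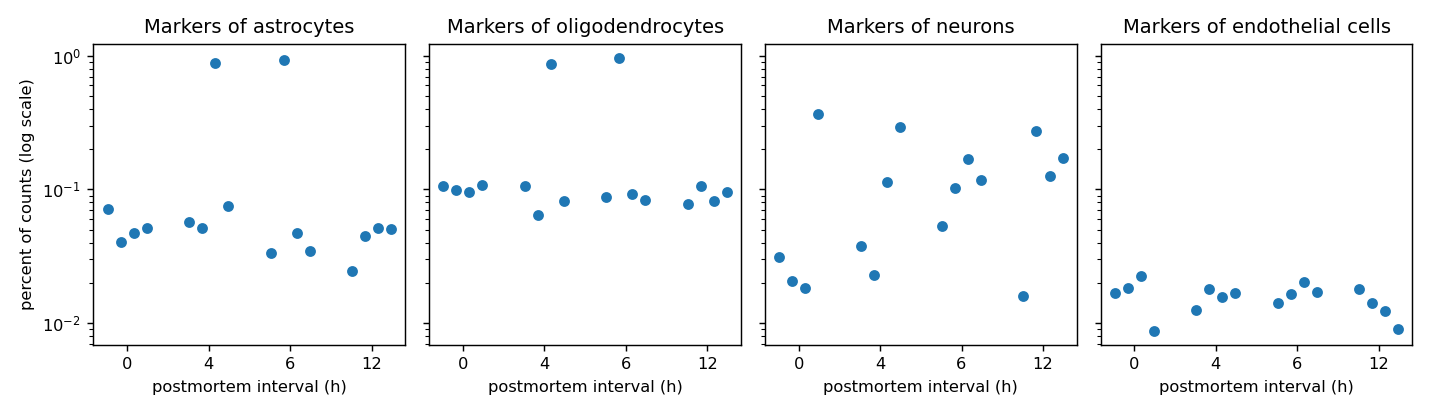
Percent of counts in marker genes of astrocytes, oligodendrocytes, neurons and endothelial cells (log axis), 1 point per library, by postmortem interval in hours. The 4 h library 3 and the 6 h library 2 stand above the other 14 libraries for astrocytes and oligodendrocytes.

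Several genes of surveying microglia stayed within narrow limits of their 0 h level. For P2ry12, a purine receptor of microglial processes, the log2 fold change was -0.00, 0.14 and 0.15 at 4, 6 and 12 h (standard error 0.16, n = 4 per interval), and its mean CPM was 5733 ± 528 at 0 h and 6378 ± 477 at 12 h. Tmem119, a microglial surface protein, gave 0.11, 0.14 and 0.09 (0.20), Cx3cr1, the fractalkine receptor, 0.08, 0.02 and 0.04 (0.15), and Csf1r, the receptor for the growth factor that keeps microglia alive, -0.15, -0.17 and 0.05 (0.17). The 95% intervals of these 4 genes excluded a change of 1 log2 unit at every interval. Sall1, a transcription factor of microglial identity, gave -0.12, -0.18 and -0.21 (0.23), Itgam, which encodes CD11b, -0.22, -0.09 and 0.10 (0.28), and Ptprc, which encodes CD45, -0.53, -0.27 and -0.03 (0.29). Actb gave 0.11, 0.01 and 0.14 (0.16). Less precise were Jun, an immediate early gene, at -0.52, -0.26 and -0.52 (0.36), Hmox1, an oxidative stress gene, at 0.39, 1.33 and 0.64, and Cirbp, a cold-inducible RNA-binding protein, at 0.50, -0.41 and 1.58, none of which passed. The values of Cirbp depended on single libraries: they were -1.9 at 4 h without the 4 h library 4 and 0.55 and 2.57 at 6 and 12 h without the 0 h library 2. Over the 26 genes of homeostatic microglia the median log2 fold change was -0.03, 0.04 and 0.09, and camera gave an adjusted p = 0.887, 0.913 and 0.332. Camera sets a list against the other genes, so this does not show that each member stayed the same. Adjusted over the list alone in edgeR, 0, 1 and 0 members were higher and 0, 0 and 0 lower. Without the 4 h library 3 and the 6 h library 2, 0, 2 and 5 were higher and 0, 0 and 1 lower.

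**Figure D2:**
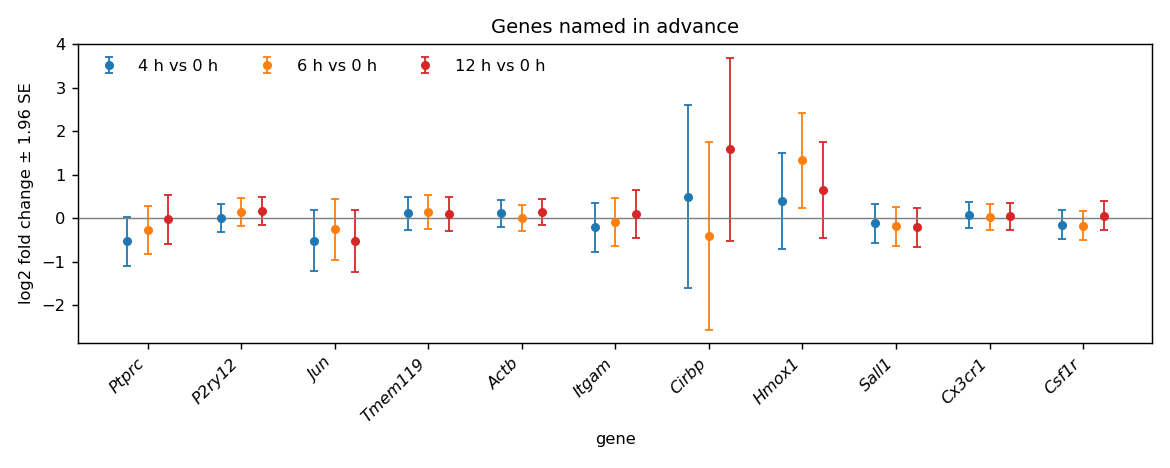
Log2 fold change against 0 h of 11 genes of the fixed panel at 4, 6 and 12 h, with bars of the normal 95% interval from the standard error (edgeR, 4 libraries per interval). P2ry12, Tmem119, Cx3cr1 and Csf1r lie between -1 and 1 with their bars, and those of Cirbp are the widest.

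After 4 h, the 2 genes called were noncoding RNA genes. Gm26917, annotated as a lincRNA (ENSMUSG00000097971, chromosome 17, 39843013 to 39846341, plus strand), rose from a CPM of 56.1 ± 40.4 to 659 ± 171 (SD, n = 4), a log2 fold change of 3.58 ± 0.41 (SE). Gm24265, annotated as a small nuclear RNA (ENSMUSG00000096243, chromosome 5, 115489459 to 115489599, plus strand), rose from 3.18 ± 3.13 to 164 ± 111, a log2 fold change of 5.73 ± 0.69. Both had an adjusted p of 1.1e-05 in edgeR and were the only genes of 6754 called. Reads of both are uncertain in origin, since small nuclear RNA genes have near-identical copies and Gm26917 lies beside CT010467.1, annotated as ribosomal RNA on the other strand (chromosome 17, 39846353 to 39848827).

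Mitochondrially encoded mRNAs, which specify subunits of the respiratory chain, rose as a list, with a mean log2 fold change of 0.79 and higher values for 8 of 8 genes (camera adjusted p = 3.8e-06, adjusted p = 0.172 with an estimated correlation). In edgeR, 6 of them passed adjusted over the list alone, and over all genes tested none did: mt-Nd1 gave 0.90 ± 0.19, mt-Nd4 0.84 ± 0.22, mt-Co1 1.11 ± 0.31 and mt-Nd6 1.35 ± 0.38. DESeq2 called mt-Nd1 (adjusted p = 0.00129), mt-Nd4 (0.0457), mt-Co1 (0.0457) and mt-Nd6 (0.0497) over all genes. Heat shock genes, mostly cytosolic and mitochondrial chaperones, rose as a list by a mean of 0.82 with 13 of 13 members higher (camera adjusted p = 4.8e-05, adjusted p = 0.174 with an estimated correlation). Hsp90ab1 gave 1.09 ± 0.26, Hspe1 1.26 ± 0.36 and Hspd1 2.03 ± 0.84, and 2 passed adjusted over the list alone and 0 over all genes tested. Without the 4 h library 3 these were 0.70, 0.84 and 0.41, and without the 0 h library 4 Hspd1 gave 3.05. Hsp90ab1 was called in edgeR without the 6 h library 2, and DESeq2 called Hsp90ab1 and Hspe1 with all libraries. Cytosolic ribosomal protein genes rose by a mean of 0.32 with 60 of 71 higher (camera adjusted p = 4.5e-06, adjusted p = 0.470 with an estimated correlation), 2 of them passing adjusted over the list alone and 0 over all genes. Their mean was 0.21 without the 4 h library 1. Rps23 gave 1.13 ± 0.24 and Rpl5 1.09 ± 0.30, and DESeq2 called both. Immediate early genes, whose transcripts appear within minutes of a stimulus and decay quickly, fell as a list by a mean of 0.46 on the log2 scale, 6 of 8 being lower (camera adjusted p = 0.0268, adjusted p = 0.220 with an estimated correlation). Junb gave -1.42 ± 0.45 and Btg2 -0.87 ± 0.41, with 1 passing adjusted over the list alone and 0 over all genes. The call of this list was lost in 13 of 16 fits that left out 1 library (means -0.48 to -0.32). It was kept without the 0 h library 3 or the 12 h library 1 or 3. Of the 35 splits of the 0 and 4 h libraries, 7 gave 4 or more lists, so chance is not excluded for the number of lists. Rnu12, which encodes the U12 small nuclear RNA, had 44 counts against 0 at 0 h and was at least 14-fold higher (floor of 3 counts over the 0 h group), without passing.

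Markers of astrocytes had a mean log2 fold change of 1.31 (camera adjusted p = 0.0750), and Aldoc, S100b and Slc1a2 gave 4.62 ± 1.49, 4.87 ± 1.49 and 3.72 ± 1.33, which rest on the 4 h library 3. Without that library and the 6 h library 2, 5 genes were called, and mitochondrially encoded mRNAs (0.65), heat shock genes (0.67) and ribosomal protein genes (0.40) passed as lists, while immediate early genes (-0.35) did not. With an estimated correlation these 3 lists had an adjusted p = 0.133, 0.364 and 0.409. Of the other lists, inflammatory cytokines had a mean of 0.03, interferon genes 0.27, unfolded protein response 0.03, apoptosis 0.02, glycolysis -0.15 and lysosome 0.11, and none passed. The 95% interval lay between -1 and 1 log2 units for 864 genes (12.8%), so for most genes a change by a fold of 2 was not excluded. DESeq2 called 19 genes, and edgeR with no filter on low counts 142.

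After 6 h, the same pair of noncoding genes and single members of the mitochondrial and ribosomal protein groups were higher than at 0 h. Gm24265 reached a CPM of 224 ± 102 (log2 fold change 6.17 ± 0.69, edgeR adjusted p = 4.7e-06) and Gm26917 612 ± 242 (3.48 ± 0.40, adjusted p = 9.8e-06). The gene mt-Nd1, a subunit of respiratory complex I (mitochondrial genome, 2751 to 3707), rose from a CPM of 1403 ± 97.3 to 2963 ± 462, by 1.08 ± 0.19 (adjusted p = 0.0113), a call lost without any one 0 h library or the 6 h library 1 or 3. Rps23, a protein of the small ribosomal subunit (ENSMUSG00000049517, chromosome 13, 90922958 to 90924950), rose by 1.19 ± 0.24 (adjusted p = 0.0432). No gene fell. The fifth smallest p was that of mt-Nd4, at 1.05 ± 0.23, which did not pass.

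As lists, mitochondrially encoded mRNAs rose by a mean of 0.86 (8 of 8 higher, camera adjusted p = 2.4e-06, adjusted p = 0.172 with an estimated correlation), with 6 passing adjusted over the list alone and 1 over all genes. Ribosomal protein genes rose by 0.46 (67 of 71 higher, camera adjusted p = 1.2e-09, adjusted p = 0.275 with an estimated correlation), with 13 passing adjusted over the list alone and 1 over all genes. Rpl5 gave 1.38 ± 0.30, Rpl39 1.11 ± 0.26 and Rplp2 1.0 ± 0.24. Heat shock genes rose by 0.88 (12 of 13 higher, camera adjusted p = 1.0e-04, adjusted p = 0.189 with an estimated correlation), with Hsp90ab1 at 1.09 ± 0.26, Hsp90aa1 at 1.13 ± 0.46 and Hspd1 at 2.02 ± 0.84, 1 passing adjusted over the list alone. Without the 6 h library 2 Hsp90aa1 gave 0.48, without the 0 h library 4 Hspd1 gave 3.07, and without the 4 h library 3 Hsp90ab1 was called. Nuclear genes of oxidative phosphorylation rose by 0.32 (57 of 73 higher, camera adjusted p = 9.9e-04, adjusted p = 0.476 with an estimated correlation), with Atp5j at 1.35 ± 0.36 and Cox8a at 1.27 ± 0.37. Antigen presentation genes rose by 0.44 (8 of 10, camera adjusted p = 0.0267, adjusted p = 0.174 with an estimated correlation), among them H2-DMb1 at 1.10 ± 0.31, a chaperone of MHC class II loading, and 1 passed adjusted over the list alone. Oxidative stress genes, targets of NRF2, rose by 0.44 (8 of 10, camera adjusted p = 0.0439, adjusted p = 0.174 with an estimated correlation), with Prdx1 at 1.31 ± 0.45. Hemoglobin and other erythroid genes rose by 1.59 (4 of 4, camera adjusted p = 0.0381, adjusted p = 0.592 with an estimated correlation), Hba-a2 giving 1.85 ± 0.87 and Hbb-bs 1.32 ± 0.76. In the oxidative phosphorylation, oxidative stress and erythroid lists 0 genes passed in edgeR adjusted over the list alone. In these, the heat shock and the antigen presentation lists 0 genes passed in edgeR over all genes tested. DESeq2 called members of some of these lists over all genes, among them Hsp90ab1, Atp5j, Cox8a and H2-DMb1. Leaving out 1 library, the oxidative stress call was lost in 11 of 16 fits and kept without the 0 h library 3, the 4 h library 1, 2 or 4 or the 12 h library 3. The erythroid call was lost in 7, without the 0 h library 1, 2 or 3, the 6 h library 2, 3 or 4 or the 12 h library 2. Antigen presentation genes lost theirs in 5, without the 0 h library 2, 3 or 4, the 4 h library 3 or the 6 h library 4. Oxidative phosphorylation genes lost theirs without the 6 h library 2 (0.14). Of 35 splits 4 gave at least 7 lists, so chance is not excluded for their number at 6 h either. The oxidative stress call also ended with a trend on transcript length and GC content removed (0.39, adjusted p = 0.105), and Prdx1 gave 0.76 without the 6 h library 2. Hba-a2 and Hbb-bs gave 1.18 and 0.84 without the 6 h library 3 and 3.29 and 2.33 without the 0 h library 4.

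Astrocyte markers (mean 1.06) and oligodendrocyte markers (1.07) were higher on average without passing, and Aldoc and Slc1a2 gave 4.91 ± 1.5 and 3.95 ± 1.34, values that rest on the 6 h library 2. Without that library and the 4 h library 3, 12 genes were called (10 higher, 2 lower), including the same 4. Mitochondrially encoded mRNAs (0.66), ribosomal protein genes (0.47) and heat shock genes (0.69) then passed as lists, and oxidative phosphorylation (0.15), antigen presentation (0.40), oxidative stress (0.41) and erythroid genes (1.62) did not. With an estimated correlation the first 3 had an adjusted p = 0.133, 0.364 and 0.364. Immediate early genes had a mean of -0.23, inflammatory cytokines 0.34 (0.08 without the 6 h library 1), interferon genes 0.12, hypoxia genes -0.06, glycolysis 0.03 and circadian genes 0.36, none of which passed. The 95% interval lay between -1 and 1 for 802 genes (11.9%). DESeq2 called 37 genes, edgeR with no filter 142, and the call of Rps23 was lost in 17 of the alternative settings.

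After 12 h, 16 genes differed from 0 h, 14 of them higher, and the added calls were mostly ribosomal protein genes. Rps23 rose by 1.42 ± 0.24 (edgeR adjusted p = 0.00397) to a CPM of 900 ± 115, from 337 ± 51.8 at 0 h. Rpl39 (1.48 ± 0.27), Rpl36a (1.31 ± 0.23), Rplp2 (1.26 ± 0.24), Rps24 (1.24 ± 0.24) and Rpl38 (1.22 ± 0.27) rose too, with edgeR adjusted p between 0.00755 and 0.0482. Tpt1, an abundant mRNA that, like those of ribosomal proteins, has a 5' oligopyrimidine tract (chromosome 14, 75845093 to 75848525), rose by 1.39 ± 0.26 (adjusted p = 0.00816). Of the mitochondrial genome, mt-Nd1 rose by 1.13 ± 0.19 (adjusted p = 0.00397), mt-Nd4 by 1.17 ± 0.23 (0.0118) and mt-Cytb by 0.94 ± 0.21 (0.0486). Leaving out 1 library, the call of mt-Cytb was lost in 13 of 16 fits and kept without the 4 h library 3 or 4 or the 6 h library 2. That of Rpl38 was lost in 12 and kept without the 0 h library 1, the 4 h library 3, the 6 h library 2 or the 12 h library 3. Those of Rplp2 and Rps24 were lost in 5, of Rpl39 in 4, of Rpl36a and mt-Nd4 in 3, of Tpt1 in 2 and of Rps23 and mt-Nd1 in none. These losses came without the 0 h library 1, 2 or 3 or the 12 h library 2, 3 or 4.

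Vgll4, a cofactor of TEAD transcription factors (ENSMUSG00000030315, chromosome 6, 114860628 to 114969994, minus strand), fell from a CPM of 137 ± 49.0 to 17.4 ± 6.77, a log2 fold change of -2.97 ± 0.56 (edgeR adjusted p = 0.00816), a call lost without the 0 h library 1 or 2 or the 12 h library 4. Among the genes called, noncoding genes had the largest rises: Gm24265 by 6.81 ± 0.68 (adjusted p = 5.9e-07) and Gm26917 by 3.82 ± 0.41 (1.8e-06). Rnu12 (chromosome 15, 83149644 to 83149794), with 73 counts against 0, was at least 28.1-fold higher (adjusted p = 0.00812), a call lost without the 0 h library 2 or 3. Gm24407, a neighbour of Gm24265 and also a small nuclear RNA gene (chromosome 5, 115490254 to 115490394), had 62 counts against 1, a ratio of 71.6 with a 95% counting interval of 12.4 to 2873 (adjusted p = 0.0305). Its call was lost in 9 of 16 fits, those without any one 0 h library, the 6 h library 3 or 4 or the 12 h library 1, 3 or 4. Gm24265, Gm26917, Gm24407 and Rpl38 at 12 h, and CT010467.1 throughout, lie outside the rule for named genes and were named after their values were seen. CT010467.1 gave 0.73 ± 0.38, 0.76 ± 0.38 and -0.03 ± 0.38 at 4, 6 and 12 h and did not pass. Relative to the library total its CPM was 1666 in the 4 h library 3 and 2059 in the 6 h library 2, against 572 to 883 in the other libraries at 4 and 6 h and 507 to 853 at 0 h.

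**Figure D3:**
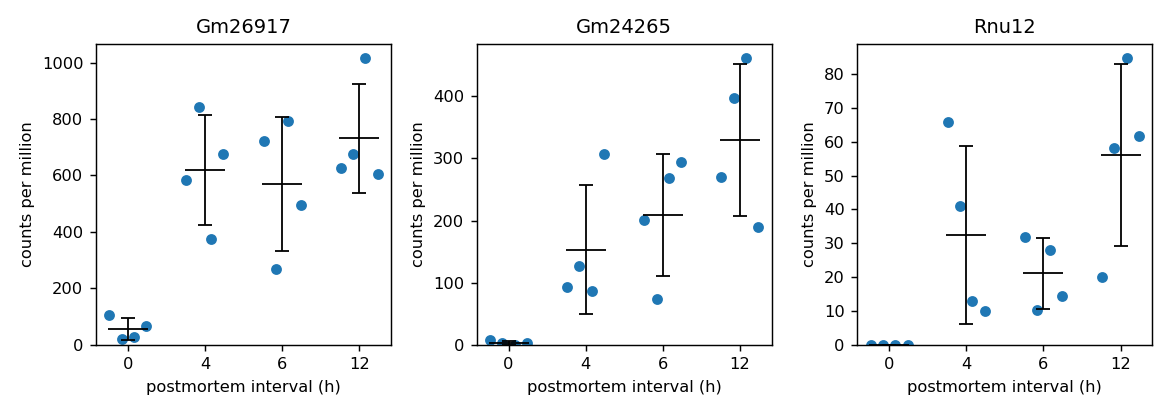
Counts of Gm26917, Gm24265 and Rnu12 per library, scaled to the library total without the normalization factors used in the text, by postmortem interval in hours, with mean ± SD of 4 libraries. Every library at 4, 6 and 12 h lies above every library at 0 h for all 3 genes.

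As lists at 12 h, ribosomal protein genes rose by a mean of 0.79, with 68 of 71 higher (camera adjusted p = 5.5e-29, adjusted p = 0.165 with an estimated correlation); 44 passed adjusted over the list alone and 6 over all genes tested. Their share of counts was 5.50% ± 0.466 (SD, n = 4) against 3.32% ± 0.332 at 0 h, each 12 h library lying above each 0 h library (exact permutation p = 0.0286, the smallest possible; adjusted over 51 tests 0.208). Mitochondrially encoded mRNAs rose by 0.92 (7 of 8 higher, camera adjusted p = 6.5e-07, adjusted p = 0.172 with an estimated correlation), with 6 passing adjusted over the list alone and 3 over all genes. Counts in mitochondrially encoded genes made up 2.27% ± 0.694 at 4 h, 2.39% ± 0.612 at 6 h and 2.19% ± 0.166 at 12 h against 1.56% ± 0.134 at 0 h, all later libraries being above all at 0 h (exact p = 0.0286 each, adjusted 0.208). The difference from 0 h fell from 0.715 to 0.369 percentage points without the 4 h library 3 and from 0.83 to 0.53 without the 6 h library 2.

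Lysosomal genes rose by 0.28 (20 of 24 higher, camera adjusted p = 0.00291, adjusted p = 0.172 with an estimated correlation), with Psap at 0.64 ± 0.19, Ctsz at 0.77 ± 0.27 and Gusb at 0.78 ± 0.33. Proteasome genes rose by 0.31 (25 of 35, camera adjusted p = 0.00684, adjusted p = 0.217 with an estimated correlation), and nuclear oxidative phosphorylation genes by 0.28 (52 of 73, camera adjusted p = 0.00128, adjusted p = 0.476 with an estimated correlation). Glucocorticoid receptor targets rose by 0.89 (7 of 9, camera adjusted p = 0.00169, adjusted p = 0.172 with an estimated correlation), among them Sult1a1 at 2.19 ± 0.77, Ddit4 at 1.86 ± 0.72 and Per1 at 1.45 ± 0.61. Genes of disease-associated microglia, described in models of neurodegeneration, rose by 0.40 (12 of 13, camera adjusted p = 0.0377, adjusted p = 0.357 with an estimated correlation), with Cd63 at 0.84 ± 0.27 and Clec7a at 2.93 ± 1.31. In these 5 lists 0 genes passed in edgeR adjusted over the list alone or over all genes. DESeq2 called members over all genes, among them Psap (adjusted p = 0.0230) and Cd63 (0.0498). The call of the disease-associated list was lost without the 0 h library 1, 2 or 4 or the 12 h library 1 or 2. With a trend on transcript length and GC content removed, the calls of oxidative phosphorylation (0.21, adjusted p = 0.111) and of disease-associated microglia (0.39, adjusted p = 0.117) ended. Heat shock genes did not pass at 12 h (mean -0.32, camera adjusted p = 0.352), nor did immediate early genes (-0.48, adjusted p = 0.0755), although 2 of these were lower adjusted over the list alone. The latter list passed with that trend removed (-0.50, adjusted p = 0.0317, adjusted p = 0.287 with an estimated correlation) and without the 12 h library 1 (-0.65), while its mean was -0.20 without the 12 h library 2. Means were 0.25 for antigen presentation, -0.02 for interferon, -0.11 for inflammatory cytokine, -0.14 for hypoxia, -0.37 for glycolysis and -0.27 for apoptosis genes, and none of these lists passed.

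Without the 4 h library 3 and the 6 h library 2, 34 genes were called at 12 h (25 higher, 9 lower), which included all 16, and the same 7 lists passed at the preset correlation. With an estimated correlation none of them did (smallest adjusted p = 0.0836, adjusted over the tests between adjacent intervals too). Among the genes gained, named after their values were seen, were Rpl31 and Rps12, and Malat1, a nuclear noncoding RNA, which was lower at -1.17 ± 0.20 (edgeR adjusted p = 5.7e-04) and with all 16 libraries gave -1.17 ± 0.29 (adjusted p = 0.104). The 95% interval lay between -1 and 1 for 762 genes (11.3%). DESeq2 called 72 genes, a fit of only the 8 libraries compared 36, edgeR with no filter 27, and the count fell to 4 without the 0 h library 2.

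**Figure D4:**
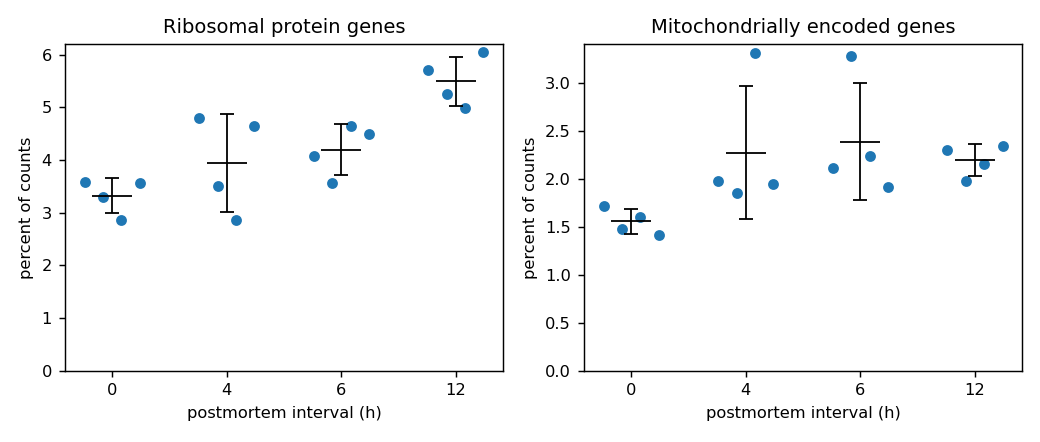
Percent of counts in cytosolic ribosomal protein genes and in mitochondrially encoded genes, 1 point per library with mean ± SD of 4 libraries, by postmortem interval in hours. At 12 h each library lies above each 0 h library for both groups.

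Between adjacent intervals edgeR called no gene with all 16 libraries and the filter on low counts. For 6 h against 4 h, 0 of 6754 genes passed in edgeR, 331 had an unadjusted p under 0.05, and DESeq2 called 0. The smallest p belonged to Suclg2 (-3.47 ± 0.84), Dnajc28 (-4.14 ± 1.04), Slc25a45 (1.16 ± 0.31), Wdyhv1 (-4.16 ± 1.16) and Tmem41b (-3.19 ± 0.88), with an adjusted p of 0.908. For 12 h against 6 h, 0 genes passed in edgeR, 439 had an unadjusted p under 0.05, and DESeq2 called 1, Gm2000. With no filter edgeR called 125 genes between 6 and 12 h (121 lower), and without the 4 h library 3 and the 6 h library 2 it called Mbd2 between 4 and 6 h. Without the 4 h library 3 alone it called 2 genes between 4 and 6 h and 3 between 6 and 12 h. Chaperone genes were among the smallest p-values without passing, Hsp90ab1 at -1.15 ± 0.27, Hspa8 at -1.45 ± 0.34 and Hsp90aa1 at -2.0 ± 0.49, beside Gm2000 at 1.31 ± 0.31 and Smc5 at 3.70 ± 0.93 (edgeR adjusted p = 0.492). In list tests added after the data were seen, heat shock genes fell by 1.21 on the log2 scale between 6 and 12 h (camera adjusted p = 6.5e-07, adjusted p = 0.215 with an estimated correlation). Glucocorticoid targets rose by 0.71 (adjusted p = 0.00291, adjusted p = 0.215 with an estimated correlation) and ribosomal protein genes by 0.33 (adjusted p = 1.2e-07, adjusted p = 0.478 with an estimated correlation). No list passed between 4 and 6 h, and without the 4 h library 3 and the 6 h library 2 the heat shock genes gave -1.0 and the glucocorticoid targets 0.99.

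Tested over all intervals together, 5 genes differed in edgeR: Gm24265 (adjusted p = 1.2e-05), Gm26917 (2.0e-05), mt-Nd1 (0.0237), Rps23 (0.0313) and the chaperone gene Hsp90ab1 (0.0455). A CPM of 994 ± 180 at 0 h stood against 2123 ± 995 at 4 h, 2118 ± 792 at 6 h and 952 ± 71.5 at 12 h for Hsp90ab1. A linear trend with hours was called for 8 genes. Rpl36a, Rps24, Tpt1, Rpl39, Rplp2 and Rpl38 rose, by 1.22 to 1.41 log2 units per 12 h, and Vgll4 fell by 2.94 (edgeR adjusted p between 0.0311 and 0.0380). Leaving out 1 library, the trend gave 0 genes (without the 0 h library 2) to 20 (without the 6 h library 2), and all intervals together 2 to 26 (26 without the 4 h library 3). Of 100 relabellings of the libraries, 11 gave at least 8 genes for the trend and 25 at least 5 over all intervals, so chance is not excluded for either count. DESeq2 called 59 genes over all intervals and 69 for the trend, and without the 4 h library 3 and the 6 h library 2 edgeR called 24 and 28. The interval accounted for 21.7% of the variance of the tested genes, against a median of 19.8% in relabelled libraries (permutation test, one-sided p = 0.0393). Leaving out 1 library, this p stayed under 0.05 in only 2 of 16 fits, without the 4 h library 3 (0.0146) or the 6 h library 2 (0.0197), and over the 1000 most variable genes it was 0.204.

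Fold changes against 0 h were correlated across genes between intervals, with Pearson's r of 0.542 for 4 and 6 h, 0.431 for 4 and 12 h and 0.471 for 6 and 12 h over 6754 genes, which are not independent replicates. Unchanged groups simulated against the same 0 h libraries gave a mean r of 0.497, 0.494 and 0.497. The covariance was 0.366, 0.292 and 0.329 against simulated values of 0.281, 0.281 and 0.283, a difference of 0.0851, 0.0102 and 0.0462. With the 0 h libraries split between the comparisons, r was 0.172, 0.0918 and 0.125. Without the 4 h library 3 and the 6 h library 2, r was 0.381, 0.410 and 0.435.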

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

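The tests of other cells, of a rise in proportion to the hours, of RNA without a poly(A) tail and of the lists without the 4 h library 3 and the 6 h library 2 were chosen after the results were seen, as were the list tests between 6 and 12 h, while the tests of transcript length and GC content were chosen after the data but before their own results were seen. A library was singled out where its gap to the nearest of the other 3 of its interval exceeded the 95% critical value of Dixon's ratio for 4 samples. This held in 51 of 376 groups (13.6%) over 18 library measures and 76 genes, where chance gives about 1 in 20 for normal values. Xist and some other genes were included after their values were seen, and several had few counts. The excess over 1 in 20 is therefore not evidence by itself. The 4 h library 3 accounted for 13 of these values and the 6 h library 2 for 12. CPM values here are relative to the library total alone.

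Astrocyte and oligodendrocyte transcripts in the 4 h library 3 and the 6 h library 2 are the first pattern. Of 29 list genes with at least 10 counts over all libraries, 27 (93.1%) had a higher share in both libraries than in each of the other 14. These libraries were singled out by the shares of the same lists, and some genes may reach 10 counts only through them. The count thus shows a rise spread over many list genes and is not separate support for an explanation. RNA of these cells may be present in both libraries, although the gate for CD45 and CD11b would remove such cells. A lower share of microglia with every other cell type raised alike is argued against by endothelial markers, which reached 0.0166% in these libraries and 0.0225% elsewhere. Markers of oligodendrocyte precursors (0.0845% and 0.0680%, at most 0.00507% elsewhere) and of ependyma (0.0512% and 0.0571%, at most 0.0195%) were raised too. So were those of mural cells (0.00146% and 0.00246%, at most 0.000723%), on few counts. RNA of further brain cell types is therefore not excluded. The delay is argued against by the other 6 libraries at 4 and 6 h, whose summed astrocyte and oligodendrocyte share reached 0.163% against 0.178% in the highest 0 h library. Free or engulfed RNA and a mixture with another sample, to which the Xist counts might also belong, were not tested and stay open.

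Gm26917, Gm24265, Gm24407 and Rnu12, near 0 or low at 0 h and counted in every later library, are the second pattern. A rise in proportion to the hours needs a log2 fold change of 1.58 between 4 and 12 h, and for Gm26917 it is argued against by a value of 0.24 ± 0.35 with an upper 95% limit of 0.96. For Gm24265 (1.08 ± 0.44, upper limit 1.99) such a rise stays possible. More RNA without a poly(A) tail in later libraries cannot be told apart from other explanations: small nucleolar RNA and replication-dependent histone genes took 0.0420% ± 0.0134 of counts later and 0.0486% ± 0.0141 at 0 h, but these shares rest on few counts. Reads from other copies, a library step shared by all 0 h libraries and the delay itself stay open, since the sources give no batch and no treatment of reads with several matches.

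Higher mRNAs of ribosomal proteins and of the mitochondrial genome are the third pattern. With a trend on transcript length and GC content removed, the mean log2 fold change at 12 h was 0.73 for ribosomal protein genes (0.79 before, SD over members 0.437 after) and 0.93 for mitochondrially encoded mRNAs (0.92 before, SD 0.399 after), which argues against such a trend as the whole cause. Without the 4 h library 3 and the 6 h library 2 the means at 4, 6 and 12 h were 0.40, 0.47 and 0.79 for ribosomal protein genes (0.32, 0.46 and 0.79 with them) and 0.65, 0.66 and 0.93 for mitochondrially encoded mRNAs (0.79, 0.86 and 0.92 with them), which argues against these libraries as the whole cause. An effect of the delay on the cells, such as slower loss of these mRNAs than of others, may remain as a hypothesis, and a difference in isolation or library preparation between the intervals was not tested.

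In the 4 h library 3, astrocyte markers took 0.878% of counts (other 4 h libraries 0.0515 to 0.0752), oligodendrocyte markers 0.867% (0.0646 to 0.106), markers of oligodendrocyte precursors 0.0845% (0 to 0.00447), of mural cells 0.00146% (0 to 0.000248) and of ependyma 0.0512% (0.000747 to 0.00397). Mitochondrially encoded genes took 3.31% there (1.85 to 1.97), and thinned to the smallest total this library held 10460 genes (9378 to 9490). Its CPM was 1262 for Aldoc (0 to 11.2), 1236 for S100b (12.4 to 35.9), 801 for Slc1a2 (7.47 to 57.1), 148 for Hspd1 (14.9 to 23.9), 214 for Psmb10 (81.9 to 98.7) and 146 for Xist (0 in the others).

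In the 6 h library 2, astrocyte markers took 0.927% (other 6 h libraries 0.0336 to 0.0475), oligodendrocyte markers 0.969% (0.0834 to 0.0924), markers of oligodendrocyte precursors 0.0680% (0 to 0.00185), of mural cells 0.00246% (0 to 0.000358) and of ependyma 0.0571% (0.00336 to 0.00573). Its CPM was 1510 for Aldoc (7.16 to 55.8), 944 for S100b (0 to 8.39), 1011 for Slc1a2 (8.39 to 22.3), 2002 for Apoe (242 to 283), 6956 for Malat1 (3015 to 3626), 499 for Trem2 (841 to 903) and 36.8 for Xist (0 in the others).

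At 0 h, library 1 stood apart with 0.400% of counts in border macrophage markers (others 0.270 to 0.276) and a CPM of 618 for Rpl36a (394 to 422), 596 for Trem2 (856 to 900), 296 for Ndufa13 (91.2 to 107) and 3643 for Maf (2537 to 2576). Maf belongs to the border macrophage list and made up most of that share. Library 4 at 0 h had 0.365% in neuronal markers (0.0183 to 0.0314), 0.755% in erythroid markers (0.0799 to 0.190) and a CPM of 36.2 for Hspd1 (4.45 to 8.82), 77.2 for Prdx1 (121 to 125), 261 for Atp5j (93.5 to 109) and 2.41 for Gm24407 (0). Library 3 at 0 h had 2115 for mt-Nd4 (1638 to 1659) and 405 for Atp5a1 (231 to 235), and library 2 had 47.1 for Cirbp (4.83 to 11.1).

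In the 4 h library 4, erythroid markers took 1.32% (0.0840 to 0.129), and CPM was 647 for Hba-a2 (14.6 to 92.8), 10240 for Hbb-bs (605 to 1002) and 81.9 for Cirbp (0 to 7.47). The 4 h library 1 had 6334 for Csf1r (4589 to 4763), and the 6 h library 4 had 42.9 for Junb (80.5 to 85.9). In the 12 h library 3, mural cell markers took 0.000314% (0 in the others), and CPM was 1016 for Gm26917 (606 to 676), 699 for Rps23 (879 to 905) and 90.9 for Gm24407 (33.2 to 36.5). The 12 h library 2 had 66.3 for Slc1a2 (0 to 9.41), and the 12 h library 4 had 17620 for Ctss (19910 to 20340).

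Between 6 and 12 h the difference itself was tested for lists, and camera singled out heat shock genes (mean log2 fold change -1.21), glucocorticoid targets (0.71) and ribosomal protein genes (0.33), at an adjusted p = 0.215, 0.215 and 0.478 with an estimated correlation.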

How the results depend on the processing

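Fits without the 4 h library 3 and the 6 h library 2 and without the length and GC trend were chosen after the data were seen, the other settings before. Simulated changes by a fold of 2 were recovered in under 5% of genes at this depth, spread and number of libraries. In no setting did a called gene or list turn direction, Gm24265 and Gm26917 were called against 0 h in every setting, and the cause of the differences below was not tested.

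With no filter on low counts, edgeR called 142 genes at 4 h (140 higher), 142 at 6 h (138 higher), 27 at 12 h (19 higher), 125 between 6 and 12 h (121 lower), 373 over all intervals and 17 for the trend. DESeq2 called 19, 37 and 72 genes at 4, 6 and 12 h (15, 31 and 60 higher), 1 between 6 and 12 h, 59 over all intervals and 69 for the trend. A fit of only the 8 libraries compared called 36 genes at 12 h. Without the 4 h library 3 and the 6 h library 2, counts were 5, 12 and 34 at 4, 6 and 12 h, 1 between 4 and 6 h (Mbd2), 24 over all intervals and 28 for the trend, lists at 6 h fell to 3, and r was 0.381 for 4 and 6 h and 0.435 for 6 and 12 h. With an estimated correlation, 0, 0 and 0 lists passed at 4, 6 and 12 h. Over the 1000 most variable genes the interval took 21.3% of the variance (permutation p = 0.204). DESeq2 size factors in edgeR gave 2, 4 and 14 genes.

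Leaving out 1 library at a time, the counts were 2 to 11 at 4 h (11 without the 6 h library 2, 5 without the 4 h library 3), 2 to 17 at 6 h (17 without the 4 h library 3, 2 without any 0 h library or the 6 h libraries 1 or 3) and 4 to 27 at 12 h (4 without the 0 h library 2, 6 without the 0 h library 3 or the 12 h library 4, 8 without the 0 h library 1, 27 without the 6 h library 2). They were 0 to 2 between 4 and 6 h and 0 to 3 between 6 and 12 h (2 and 3 without the 4 h library 3), 2 to 26 over all intervals (26 without the 4 h library 3; 12 of 16 libraries moved it by over 1.5 times) and 0 to 20 for the trend (0 without the 0 h library 2, 20 without the 6 h library 2; 13 of 16). Lists at 6 h numbered 4 to 8 (4 without the 0 h library 2 or the 6 h library 2). The variance share was 21.8% to 23.3%, and its p stayed under 0.05 only without the 4 h library 3 (0.0146) or the 6 h library 2 (0.0197). Over named genes these fits gave 2313 same, 88 weaker, 19 stronger and 44 moved values.

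The length and GC trend removal ended the list calls of oxidative phosphorylation (0.28 to 0.21, adjusted p = 0.111) and disease-associated microglia (0.40 to 0.39, adjusted p = 0.117) at 12 h and oxidative stress (0.44 to 0.39, adjusted p = 0.105) at 6 h, and immediate early genes at 12 h gained one (-0.48 to -0.50, adjusted p = 0.0755 before and 0.0317 after, adjusted p = 0.287 with an estimated correlation).

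With the replicate number as a block, counts were 2, 3 and 16 genes at 4, 6 and 12 h, 0 and 0 between adjacent intervals, 6 over all intervals and 9 for the trend, with 4, 6 and 8 lists. Same-numbered libraries showed no strong shared deviation: 0 of 24 correlations were over 0.1 (-0.151 to 0.0899). In 9 of 24 the same number was the best match among the 4 libraries of the other interval. No pairing by number was shown, and a weak one is not excluded.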

Other observations

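The tests of gene classes were chosen after the data were seen, while the test of nuclear against cytosolic RNA and the splits of the libraries were chosen before their results were seen. Gene classes that often hold unspliced or nuclear RNA were smaller in the later libraries. Genes of the class TEC, which await experimental support, took 0.840% ± 0.163 of counts at 0 h (SD, n = 4) and 0.704%, 0.510% and 0.442% at 4, 6 and 12 h, all libraries at 6 and 12 h lying below all at 0 h. Antisense genes took 0.306% at 0 h and 0.208% at 12 h, and lincRNA genes 1.16% and 0.759%. Malat1, an abundant lincRNA gene, had a CPM of 7309 ± 2970 at 0 h and 3240 ± 571 at 12 h. Its fall was about as large as that of the whole lincRNA class, so a fall across lincRNA genes was not shown. Small nuclear RNA genes took 0.0151% at 0 h and 0.0582% at 12 h. Gm24265, Rnu12 and Gm24407, described above, made up nearly all of this difference, so a rise across the class was not shown. For TEC and antisense genes and small nuclear RNA genes at 12 h the exact permutation p was 0.0286, the smallest possible, and 0.122 adjusted over 30 tests, so none passed.

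A shift between nuclear and cytosolic RNA that differs between libraries may be a candidate explanation. It needs opposite deviations of the TEC and ribosomal protein shares within intervals, and Pearson's r was -0.16 over 16 libraries (permutation p = 0.619; Spearman's rho -0.17, p = 0.558) and -0.25 without the 2 farthest. This leaves the question open, since a weak relation was neither shown nor excluded.

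At 12 h, lymphocyte markers took 0.0289 percentage points more of the counts than the 0.0525% at 0 h, and border macrophage markers 0.0936 points less than 0.305%, with all 4 libraries on one side of those at 0 h (exact permutation p = 0.0286, adjusted over 51 tests 0.208, so neither passed). Ighm, an immunoglobulin gene of the lymphocyte list, gave a log2 fold change of 0.66 ± 0.25, and Maf, of the macrophage list, -0.49 ± 0.21. Maf made up most of the macrophage share: in the 0 h library 1 its CPM relative to the library total was 3643, where the share was 0.400%. That share therefore mostly follows the level of this gene and does not show fewer border macrophages at 12 h. Of 8 circadian genes, 7 were higher and 1 lower at 12 h (mean log2 fold change 0.40, median 0.67), and the list did not pass (camera adjusted p = 0.22). Per1 gave 1.45 ± 0.61, Nr1d2 1.5 ± 0.64 and the lower gene, Clock, -1.72 ± 0.57, with 1 passing adjusted over the list alone and 0 over all genes.

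Other splits of the libraries were compared with the real one. For 4, 6 and 12 h against 0 h, only 1, 1 and 1 of 35 splits, the real ones, gave as many called genes (2, 4 and 16). Other splits gave at most 0, 0 and 1. Chance is thus less likely for these counts but not excluded. A share of 1 in 35 is the smallest these splits can give, and it was not adjusted over the comparisons. The same holds for the lists at 12 h, where 1 of 35 splits gave 7 and the others at most 4 at the preset correlation. With an estimated correlation 0 lists passed at 12 h (smallest adjusted p = 0.165), and no splits were run with it. Chance is not excluded either for the lists at 4 h (7 of 35 splits gave 4 or more, at most 8) or 6 h (4 of 35 gave 7). Nor is it for all intervals together (25 of 100 relabellings gave 5 or more, at most 40) or the trend (11 of 100 gave 8 or more, at most 53). Between 4 and 6 h and between 6 and 12 h, 35 and 35 of 35 splits gave at least the real count of 0, with at most 27 and 1. Splits that called many more genes than the real one point to a structure of the samples, and the split with 27 genes had the 4 h library 3 and the 6 h library 2 on the same side.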
